A study of Homo sapiens with 3 samples.

How the data were processed

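Total RNA of KMS12PE, an established human multiple myeloma cell line, was measured after 5 days with no drug (vehicle), with melphalan at 2 μM, or with adriamycin at 50 nM. Melphalan is a DNA-crosslinking alkylating agent, and adriamycin (doxorubicin) is an anthracycline that poisons topoisomerase II. Each group holds 1 array, so 3 arrays were analysed. Per the labels' protocols, RNA was purified on silica columns, its quality was checked on a Bioanalyzer, and Cy3-labelled cRNA was made with a low-input amplification kit. The arrays are 1-colour Agilent expression arrays with 62976 spots, of which 60901 are not controls and carry 58201 probes.

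The deposited spot intensity values come from Agilent Feature Extraction version 11.5.1.1 per the file headers, while the submitters' processing notes name version 9.1. The processed intensity was background-subtracted and detrended within each array, was not normalized between arrays, and was written to 3 significant digits, per the file headers and the values. Spots near background carry a surrogate value set by that software. Probe positions are on hg19, per the file headers. The authors' deposited value table is on the log2 scale. Set against the scanner values over 58341 probes, each of its columns equalled the log2 of a probe's mean processed signal minus 1 constant per array, within 0.02 for 99.8% of probes. Its 75th percentile was 0 in each column and its medians were -3.88 for vehicle, -3.71 for melphalan and -3.76 for adriamycin. Genes were not centred in it, and its direction was that of the scanner signal.

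The values used here are log2 of the processed signal minus the array's log2 75th percentile over all non-control probes, with the spots of a probe averaged. Of the non-control spots, 48.0% on the melphalan array, 49.1% on the vehicle array and 49.6% on the adriamycin array were well above background, each below 50%. The 75th percentile over all probes had been fixed before the data were examined and was kept, and the percentile over probes detected on all arrays was therefore added as an alternative. Control spots and spots with an outlier flag were left out. No spot was saturated. A gene was represented by 1 probe, the one with the highest mean signal over the 3 arrays. Names were updated through a RefSeq gene table of assembly GRCh38.p14, used for names alone. Of 56694 named probes, 31235 matched by accession, 3275 by symbol and 475 by synonym, and 21709 kept the array's name. The remaining 1507 probes had no gene name. The universe held the 22621 of 41877 gene names whose probe was well above background on at least 1 array.

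A gene was called where its log2 difference was at least 1 in size. With 1 array per group there was no test, no p-value and no spread between replicates, and the number of arrays limits the precision. A gene not well above background on 1 array of a pair has only a bound. Its fold, written "at least", sets the brighter array against the higher of the dim probe's own signal and the lowest signal among probes well above background on that array. No fold was given where both arrays were dim. Technical error came from 300 probes printed in 10 spots each. The resulting error of a log2 difference of a single-spot probe, called the spot error below, was 0.09 at signals above 2, 0.11 at 0 to 2, 0.17 at -2 to 0 and 0.51 below -2, on the normalized log2 scale. It covers spot noise within an array and nothing between cultures. Different probes of a gene differed more, with an SD of 0.43 for melphalan over vehicle.

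The 30 gene lists were fixed before the data were examined, and each median is given with its percentile among 10000 random lists of the same size matched on mean signal in 20 bins. That percentile describes these arrays. Lists of fewer than 5 members in the universe were to be left out, and none was. The named genes followed a rule fixed at the same time. For each drug against vehicle it took the 10 largest and 10 smallest log2 differences among called protein-coding genes well above background on both arrays, and the 5 largest at-least folds each way. It took 5 of each kind for adriamycin against melphalan, the 4 members of each list with the largest absolute log2 difference averaged over both drugs, and a set of genes given whatever their values (CDKN1A, MDM2, GDF15, FAS, TNFRSF10B, MICA, MICB, ULBP1, PVR, CD38, TNFRSF17, SDC1, IRF4, MYC, MCL1 and BCL2). The text names a part of these, and adds other members of the lists as examples chosen after their values were seen. Y-linked genes and XIST were not named. Genes with near-identical relatives, such as HLA-DRB1, C4B, DAZL and the histones, are uncertain, since a probe can bind several of them.

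The calls were tested on simulated data. With spot noise alone plus 200 genes changed in the melphalan over vehicle comparison, run on 22621 genes, all 50 genes at each of the log2 changes 1.5, -1.5, 3 and -3 were recovered, and 195 unchanged genes were called. The changed genes were drawn from those well above background with vehicle at a normalized signal above -2. Recovery of genes dim with vehicle was therefore not tested. Of 20 random lists of 25 genes, 1 lay outside the central 95% of random lists before a shift of 1 was added and all 20 lay above that range after it. The alternatives were scaling on the median, normexp background correction (offset 50) with quantile normalization, quantile normalization of the processed signal, the deposited value table, genes well above background on all 3 arrays, no filter on dim probes, the mean of a gene's probes, and a log2 threshold of 1.5. Scaling on probes detected on all arrays and scaling on 7 spiked-in control probes were added after seeing the data. The 3 arrays lay on 1 slide scanned in 1 session, so slide and scan do not differ between groups, and an array's position on the slide cannot be told apart from its group. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1.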

Results

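Gene expression was compared between KMS12PE myeloma cells kept for 5 days with no drug (vehicle), with melphalan at 2 μM, and with adriamycin at 50 nM. Each condition was measured on 1 array, so no difference below has a replicate check, and all statements describe these 3 arrays. The 75th percentile of the processed signal was 124 on the vehicle array, 97.6 on the melphalan array and 109 on the adriamycin array. Genes well above background numbered 20620, 20246 and 20906, respectively, and 18790 genes were so on all 3 arrays. Values are log2 differences of normalized signal unless a fold is stated.

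The melphalan array was compared with the vehicle array to show which transcripts differed after 5 days of an alkylating drug. Of 22621 genes, 2477 were at least 2-fold higher and 1921 at least 2-fold lower with melphalan. CFB, which encodes complement factor B, had the largest measured difference, at 7.03 (130.3-fold, spot error 0.14, probe on hg19 chromosome 6 from 31918992 to 31919147). CCL17, a chemokine gene, was 128-fold higher (chromosome 16, 57449888 to 57449947), and C4B, a complement gene whose probe can also bind its close relative C4A, was 6.71 higher. The germ cell gene DAZL (6.41), the nuclear receptor gene NR4A2 (6.41), the cytokine gene LTB (6.33), IL4I1 (6.27), TNNI2 (6.19), SH3BP5 (6.16) and ABTB2 (6.88) completed the 10 largest. Genes not well above background with vehicle included CCR9, a chemokine receptor gene, at least 54.3-fold higher, and IL2RA, the interleukin 2 receptor alpha chain gene, at least 49.6-fold higher. At the other end KLHDC7B was 5.19 lower (log2 difference -5.19). GDF15, a stress-induced cytokine gene, had a difference of -4.91 (30.1-fold lower, spot error 0.10, chromosome 19 from 18499890 to 18499949). The pseudokinase gene TRIB3 stood at -4.56, ANXA1 at -4.61, LAIR1 at -4.87, ATF3 at -4.15, DDIT3 at -4.10 and IDH1 at -4.09. BCAT1, a branched-chain amino acid transaminase gene, was at least 18.4-fold lower and not well above background with melphalan.

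Antigen presentation genes were higher with melphalan. Of 21 measured members 15 were at least 2-fold higher, none was at least 2-fold lower, and the median was 1.29 (0.82 under spiked-in scaling, percentile 100.0 of matched random lists). CIITA, the transactivator of HLA class II genes, was 6.15 higher (71.1-fold, spot error 0.14, chromosome 16 from 11018667 to 11018726). HLA-DRA was 4.38 higher (20.8-fold, chromosome 6 from 32412448 to 32412507), HLA-DQA1 4.60, HLA-DMB 4.43 and the invariant chain gene CD74 3.78. HLA-DRB1 was 5.05 higher, with a probe that can bind its paralogues. HLA-B stood at 1.29 and HLA-C at 1.18. NF-kB target genes had a median of 1.81, or 1.54 with dim members at their bounds and 1.03 under normexp (percentile 100.0), and 12 of 19 were at least 2-fold higher. Among them were LTB, EBI3 (3.99) and ICAM1 (2.56), and TNF was at least 22.8-fold higher. Cell adhesion and migration genes had a median of 1.59 (1.57 with bounds, 0.52 under normexp), with 15 of 20 members well above background on vehicle, 11 of 20 at least 2-fold higher and 2 lower. PECAM1 was 5.01 higher, and the chemokine receptor genes CCR1 and CCR7 were at least 8.41-fold and 7.87-fold higher.

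Plasma cell and B lineage genes had a median of 1.04 (0.56 under spiked-in scaling), with 10 of 20 at least 2-fold higher and 2 lower. The transcription factor gene SPIB was 3.16 higher, the immunoglobulin J chain gene JCHAIN 2.74 and SLAMF7 1.91. The lower members were MZB1 at -1.05 and POU2AF1 at -1.32. Of the surface proteins targeted in myeloma therapy, CD38 stood at 1.56, TNFRSF17 (BCMA) at 0.24 and SDC1 (CD138) at 0.30. IRF4 stood at 0.62 and MYC at -0.07. Interferon-stimulated genes had a median of 0.55 (0.64 with bounds, 0.26 under normexp, 0.0757 under spiked-in scaling, percentile 99.95), with 10 of 24 at least 2-fold higher and none lower. IFI27 was 3.73 higher, IFI6 2.88 and MX1 2.46. Markers of other cell types were also measured. Of 13 monocyte and 13 fibroblast markers on the array, 5 of each were well above background on at least 1 array. Of 5 monocyte and macrophage markers above background 4 were at least 2-fold higher (median 2.46, 2.24 with bounds and 0.39 under normexp), among them TYROBP at 2.46 and CSF1R at least 6.56-fold, and 2 of the 5 were above background with vehicle. T cell markers had a median of 0.52 (0.64 with bounds, 0.20 under normexp, 0.0506 under spiked-in scaling) with 4 of 12 higher, among them LCK at 3.89. The 5 fibroblast markers had a median of 1.52 (0.94 with bounds, 0.15 under normexp, 3 of 5 above background with vehicle), with SPARC at 1.64, and the 8 epithelial markers a median of 0.53 (0.24 under normexp, 0.0593 under spiked-in scaling), with the cadherin gene CDH1 at least 34.8-fold higher and the splicing regulator gene ESRP1 at least 9.63-fold lower.

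Replication-dependent histone genes were lower with melphalan. Their median was -1.76 (percentile 0.0), and 21 of 32 were at least 2-fold lower and 1 higher. The linker histone genes H1-5 and H1-3 stood at -3.96 and -3.67, and histone probes can bind related copies. How well the cRNA labelling captured histone transcripts was not examined, so the values describe labelled signal. Unfolded protein response genes had a median of -0.98 (percentile 0.0), with 13 of 26 at least 2-fold lower and none higher. TRIB3, ATF3 and DDIT3 led this list, and PPP1R15A stood at -2.84. Homologous recombination and Fanconi anaemia repair genes had a median of -0.76 (-0.49 under normexp, -1.23 under spiked-in scaling, percentile 0.01), with 8 of 29 at least 2-fold lower and none higher, including BRCA1 at -1.61. DNA replication and S phase genes had a median of -0.55 (-0.43 under normexp, -1.03 under spiked-in scaling, percentile 0.02), with 7 of 37 lower, including PRIM1 at -2.21 and CCNE2 at -1.94. Other DNA repair genes had a median of -0.34 (-0.18 under normexp, -0.82 under spiked-in scaling, percentile 2.53), with 5 of 30 lower and 1 higher. Mitosis genes had a median of -0.22 (-0.0954 under the percentile over detected probes, -0.69 under spiked-in scaling, percentile 18.5), and 33 of 34 lay within 2-fold of vehicle.

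The p53 target genes went both ways with melphalan. Of 35 members 11 were at least 2-fold higher and 5 lower, and the median of 0.27 (percentile 99.0) became -0.20 when arrays were scaled on spiked-in controls. CDKN1A, the cyclin-dependent kinase inhibitor p21 gene, was 1.02 higher and MDM2, which encodes the p53 ubiquitin ligase, 1.86, while GDF15 and GADD45A (-2.72) were lower. FAS was 1.29 higher and TNFRSF10B, another death receptor gene, stood at -1.24. BCL2 family genes had a median of 0.43, which became -0.05 under spiked-in scaling. PMAIP1 (NOXA) was 2.55 higher, BIK 1.75, BCL2L11 (BIM) 1.65 and MCL1 1.34, and BCL2 stood at 0.56. Ligands of NK and T cells had a median of 0.35, or -0.12 under spiked-in scaling and 0.60 with the mean of a gene's probes, with 5 of 17 at least 2-fold higher. CD86 was 2.74 higher and NECTIN2 1.58, MICA stood at -0.32 and MICB at -0.75. ULBP1 was not well above background with melphalan and at least 1.65-fold lower, below the threshold. PVR was not well above background on any array.

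Immediate early genes had a median of 0.70 with melphalan (0.61 with bounds), which became -0.0104 over genes well above background on all 3 arrays, with 8 of 18 at least 2-fold higher and 5 lower, and senescence-associated secreted factor genes 0.60 (0.19 under normexp, 1.16 over genes above background on all 3 arrays), with 4 of 9 higher and 2 lower. Of 26 secreted factor genes on the array, only these 9 were well above background on at least 1 array. Medians were 0.38 for lysosome and autophagy genes, 0.36 for glycolysis, 0.30 for erythroid and megakaryocyte markers, 0.20 for cancer testis antigens, 0.19 for cholesterol synthesis, 0.18 for cytosolic ribosomal proteins and 0.14 for oxidative phosphorylation. All 7 of these took the other sign under spiked-in scaling, and oxidative phosphorylation also with scaling on the median. MYC target and ribosome biogenesis genes had a median of -0.19 (range over the alternatives -0.66 to -0.0695), oxidative stress genes -0.20 (-0.68 to -0.0609) and drug transporter genes -0.16 (-0.63 to 0.15), the last taking the other sign under normexp and with the mean of a gene's probes. Within these lists the cystine transporter gene SLC7A11 was 3.85 lower (log2 difference -3.85) and SLC7A5, an amino acid transporter that also carries melphalan, stood at -2.31. Among calls 56.3% were higher with melphalan. This share was 42.1% with scaling on the median, 66.4% with the percentile over detected probes and 22.2% with spiked-in scaling, which moved the median of all genes by -0.17, 0.12 and -0.47. Simulated unchanged arrays with spot noise gave means of 97.7 genes higher and 96.2 lower.

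**Figure D1:**
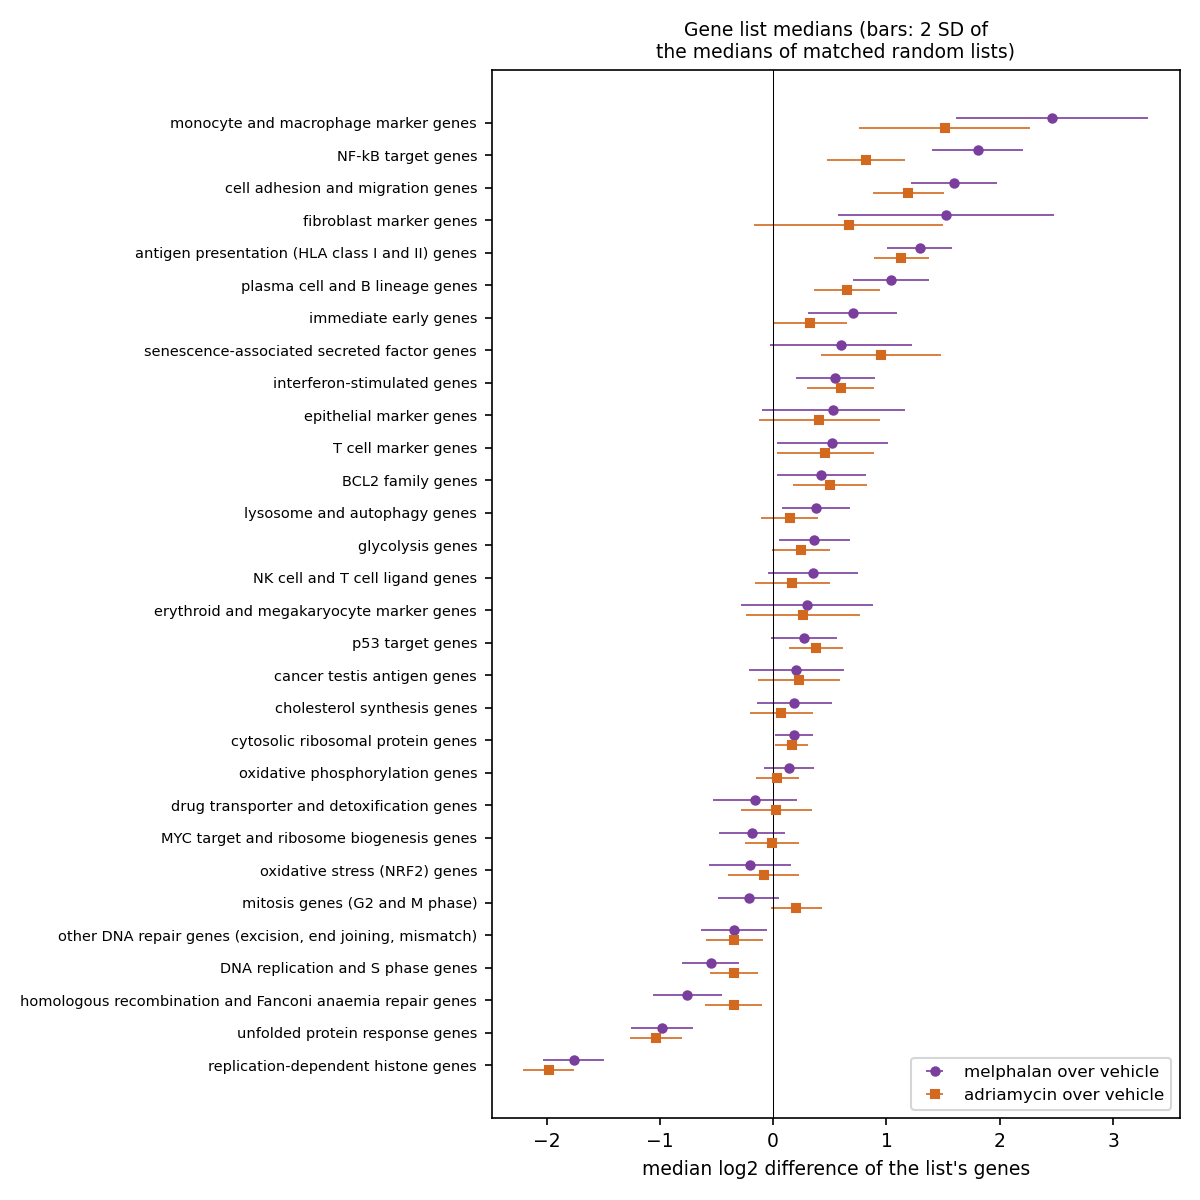
Median log2 difference (horizontal axis) of each of the 30 gene lists for melphalan over vehicle (circles) and adriamycin over vehicle (squares), with bars of 2 SD of the medians of matched random lists and not of replicates. Histone genes lie lowest (-1.76 and -1.98) and keep their sign under every scaling tried, whereas 10 melphalan and 6 adriamycin medians change sign when scaled on spiked-in controls.

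Adriamycin was compared with the same vehicle array. At least 2-fold higher were 1930 genes, and 1474 were at least 2-fold lower. NR4A2 was 5.70 higher (52.1-fold, spot error 0.37, chromosome 2 from 157181727 to 157181786). CREB3L3, a transcription factor gene, was 5.46 higher, DAZL 5.22, CFB 5.20, ABTB2 5.18, LRG1 5.13, CCL17 4.89, C4B 4.87, CIITA 4.73 and the phospholipase gene PLAAT4 4.72. KCNQ1, not well above background with vehicle, was at least 27.9-fold higher. The lowest differences were those of H1-5 (-4.19, 18.3-fold lower, chromosome 6 from 27834629 to 27834688), GDF15 (-3.78), ANXA1 (-3.77), H1-3 (-3.69), H1-4 (-3.55), KLHDC7B (-3.41), H2BC7 (-3.38), TRIB3 (-3.30), ATF3 (-3.23) and PPP1R15A (-3.22). ESRP1 was at least 11.7-fold lower.

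Histone genes had the lowest list median with adriamycin, -1.98 (percentile 0.0), with 23 of 32 at least 2-fold lower and 1 higher. Unfolded protein response genes followed at -1.04 (percentile 0.0), with 13 of 26 lower and none higher, DDIT3 standing at -2.51. Homologous recombination genes had a median of -0.35 (range over the alternatives -0.55 to -0.25, percentile 0.56) with 1 of 29 at least 2-fold lower, BRCA1 at -1.25. DNA replication genes had a median of -0.35 (-0.54 to -0.24, percentile 0.17) with 5 of 37 lower, CCNE2 at -2.33, and other DNA repair genes -0.34 (-0.54 to -0.22, percentile 0.56) with 2 of 30 lower and 1 higher. Mitosis genes had a median of 0.21 (0.0866 with scaling on the median, 0.00963 under spiked-in scaling, percentile 98.4), and PLK1, at 1.01, was the member past 2-fold. Antigen presentation genes were higher, with a median of 1.13 (percentile 100.0) and 11 of 21 at least 2-fold higher and none lower. HLA-DRA was 3.33 higher, HLA-DQA1 3.27 and CD74 3.04. Cell adhesion genes had a median of 1.19 (0.96 with bounds, 0.34 under normexp) with 10 of 20 higher and 3 lower, PECAM1 being 4.16 higher. NF-kB target genes had a median of 0.82 (0.78 with bounds, 0.48 under normexp, percentile 99.99) with 8 of 19 higher and none lower. EBI3 was 3.20 higher and ICAM1 1.82. Plasma cell and B lineage genes had a median of 0.65 (0.29 under normexp) with 5 of 20 higher and 2 lower, and interferon-stimulated genes 0.59 (0.45 with bounds, 0.31 under normexp) with 8 of 24 higher and none lower. JCHAIN was 2.78 higher, SPIB 2.54 and IFI27 3.54.

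Among p53 targets 6 of 35 were at least 2-fold higher with adriamycin and 4 lower, with a median of 0.38 (0.23 with bounds, 0.0783 over genes above background on all 3 arrays, percentile 99.9). MDM2 was 1.05 higher and CDKN1A stood at 0.69, FAS at 0.87 and TNFRSF10B at -0.85. BCL2 family genes had a median of 0.50 (0.30 under normexp) with 4 of 17 higher and none lower, MCL1 at 1.27 and BCL2 at 0.22. Ligands of NK and T cells had a median of 0.17, or -0.03 under spiked-in scaling. MICA stood at -0.58 and MICB at -0.67, and ULBP1 was at least 2.00-fold lower. CD38 stood at 0.85, SDC1 at -0.09, TNFRSF17 at -0.96, IRF4 at -0.31 and MYC at 0.30. Senescence-associated secreted factor genes had a median of 0.95 (0.28 under normexp, over 9 of the 26 on the array) with 3 of 9 higher and 2 lower, and immediate early genes 0.33 (0.25 with bounds, 0.11 over genes above background on all 3 arrays) with 6 of 18 higher and 4 lower. Of the markers of other cell types, monocyte genes had a median of 1.51 (0.36 under normexp, 3 of 5 higher, CSF1R at least 12.6-fold), T cell genes 0.46 (0.13 under normexp, 5 of 12 higher), fibroblast genes 0.67 (0.40 with bounds, 0.0255 under normexp) and epithelial genes 0.41 (0.21 under spiked-in scaling). The medians were 0.26 for erythroid genes (0.0523 under normexp), 0.24 for glycolysis and 0.23 for cancer testis antigen genes (0.0486 and 0.0343 under spiked-in scaling), and -0.09 (-0.04 with bounds) for oxidative stress genes, which took the other sign under the percentile over detected probes. They were 0.16 for ribosomal proteins, 0.15 for lysosome and autophagy, 0.07 for cholesterol synthesis, 0.04 for oxidative phosphorylation, 0.03 (0.05 with bounds) for drug transporters and -0.01 for MYC targets. The first 5 of these took the other sign under spiked-in scaling and the last under normexp. Cholesterol synthesis, oxidative phosphorylation and drug transporters also did so with scaling on the median. Drug transporters also did so under normexp, quantile normalization and over genes above background on all 3 arrays. MYC targets also did so under quantile normalization and the percentile over detected probes. Of the calls 56.7% were higher, against 45.1% with scaling on the median, 64.4% with the percentile over detected probes and 38.0% with spiked-in scaling, which moved the median of all genes by -0.12, 0.09 and -0.20. Simulated unchanged arrays gave means of 95.2 genes higher and 95.4 lower.

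The drugs shared many calls. Both comparisons called 1453 genes higher and 1111 lower, against 211 and 125 for independent lists of these sizes. Simulated unchanged arrays sharing a vehicle array gave means of 16.1 and 19.4. Log2 differences correlated across genes with r = 0.83, and genes are not independent replicates. The simulated r was 0.50. The covariance was 0.94 against a simulated 0.04. The simulation held spot noise alone and no variation between cultures. The vehicle array could not be split, so part or all of the excess may come from that shared array. Of the genes higher with both drugs, 73.4% differed more with melphalan, with medians of 2.04 for melphalan and 1.69 for adriamycin. Of the genes lower with both, 66.1% differed more with melphalan (medians -1.69 and -1.46). Spiked-in scaling moves every melphalan difference by -0.47 and every adriamycin difference by -0.20. For these same genes it narrows the first gap between medians and widens the second, and the shares were not recomputed under it. Genes called in opposite directions numbered 3. TLR1 stood at -1.03 with melphalan (spot error 0.38) and 1.02 with adriamycin (spot error 0.15). SRPK3 was 1.23 higher with melphalan (spot error 0.38) and at least 2.14-fold lower with adriamycin, and the third was a long noncoding RNA. These values or bounds lie near the threshold, and spot noise alone gave calls in each simulated comparison.

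**Figure D2:**
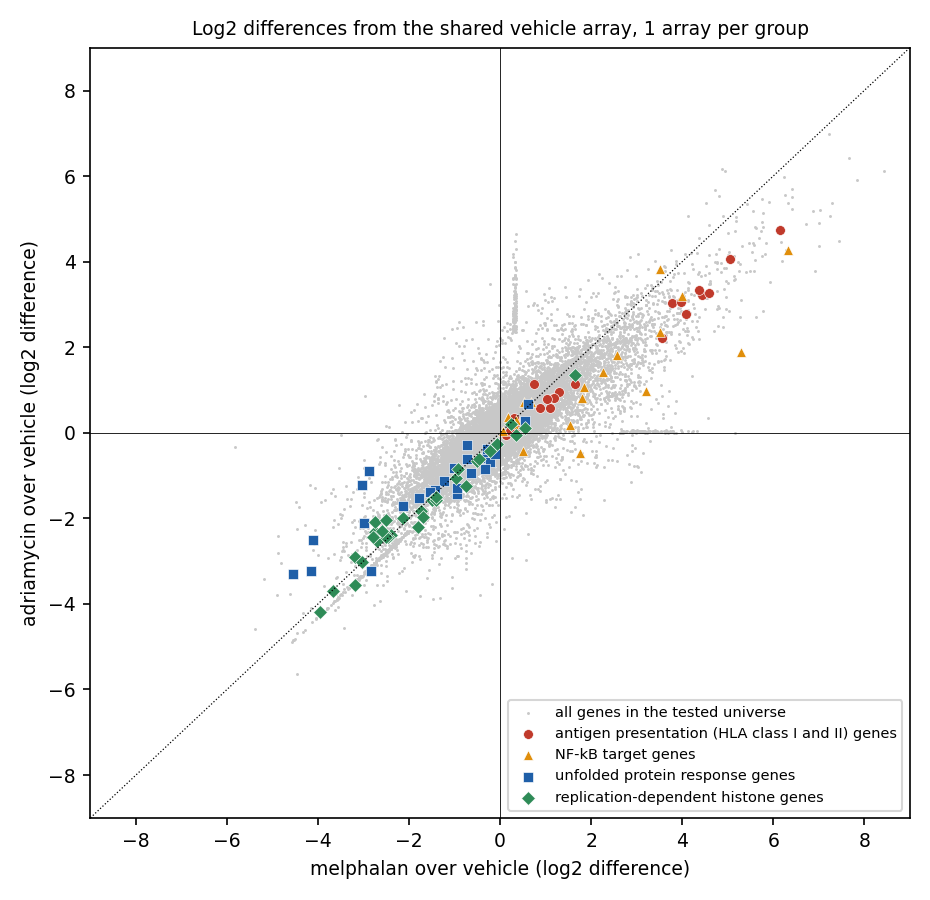
Log2 difference over vehicle with melphalan (horizontal axis) and with adriamycin (vertical axis) for the genes of the universe, with 4 gene lists marked and a dotted line at equal differences. Antigen presentation and NF-kB target genes lie mostly upper right and histone and unfolded protein response genes lower left, r is 0.83 across genes, and straight bands come from dim spots with surrogate signals.

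The drugs were set against each other on their own arrays, without the vehicle array. At least 2-fold higher with adriamycin than with melphalan were 287 genes, and 733 were at least 2-fold lower. INHBE, an activin subunit gene, was 2.36 higher (chromosome 12 from 57850864 to 57850923), SLC7A11 2.27, the argininosuccinate synthase gene ASS1 2.08, LAIR1 2.07 and TLR1 2.05, and BCAT1 was at least 14.6-fold higher. TNF was 3.41 lower with adriamycin (log2 difference -3.41, chromosome 6 from 31545837 to 31545896), IL2RA stood at -2.97, PNOC at -2.93, GALNT16 at -2.91 and MIA at -2.65. NF-kB target genes had a median of -0.78 (-0.51 under spiked-in scaling, percentile 0.0), with 6 of 19 at least 2-fold lower and none higher. Antigen presentation genes had a median of -0.50 (-0.22 under spiked-in scaling) with 6 of 21 lower and none higher, CIITA at -1.42. Plasma cell and B lineage genes had a median of -0.45 (-0.17 under spiked-in scaling) with 3 of 20 lower and none higher. Mitosis genes had a median of 0.44 (range over the alternatives 0.33 to 0.72, percentile 100.0) and 33 of 34 lay above 0, although none was past 2-fold. Homologous recombination genes had a median of 0.29 (0.18 to 0.57) and DNA replication genes 0.19 (0.10 to 0.46). MYC targets had a median of 0.32 (0.29 to 0.60), with 23 of 25 above 0. Unfolded protein response genes had a median of 0.10 (0.0684 to 0.38, percentile 89.1), with 4 of 26 at least 2-fold higher, DDIT3 at 1.59. Fibroblast markers had a median of -0.66 (-0.62 with bounds, -0.0918 under normexp). Immediate early genes had a median of -0.42, interferon-stimulated genes -0.31, and NK and T cell ligands -0.28 (-0.30 with bounds), which were -0.14, -0.0341 and -0.00519 under spiked-in scaling. Oxidative stress genes had a median of 0.12 (0.0876 to 0.40), other DNA repair genes 0.07 (0.0186 to 0.35), cancer testis antigens 0.03 and ribosomal proteins 0.01, the last 2 taking the other sign under the percentile over detected probes. Cancer testis antigens also did so under normexp and quantile normalization. The remaining medians all took the other sign under spiked-in scaling. These were epithelial -0.23 (-0.21 with bounds), secreted factor -0.21 (-0.01), adhesion -0.20 (-0.23), p53 target -0.18, monocyte -0.16 (-0.69 over genes above background on all 3 arrays), lysosome -0.14, erythroid -0.14, oxidative phosphorylation -0.10, histone -0.08, cholesterol -0.08, glycolysis -0.06, T cell -0.06 (0.14 with bounds), BCL2 family -0.04 and drug transporter genes -0.03. BCL2 family and drug transporter genes also did so with scaling on the median. T cell genes also did so under normexp, quantile normalization and the mean of a gene's probes. The doses were 2 μM of one drug and 50 nM of the other, so the sizes describe these doses alone. Of these calls 28.1% were higher, against 68.5% under spiked-in scaling, which moved the median of all genes by 0.28, and 16.1% under normexp with quantile normalization. Simulated unchanged arrays gave means of 95.9 genes higher and 98.0 lower.

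**Figure D3:**
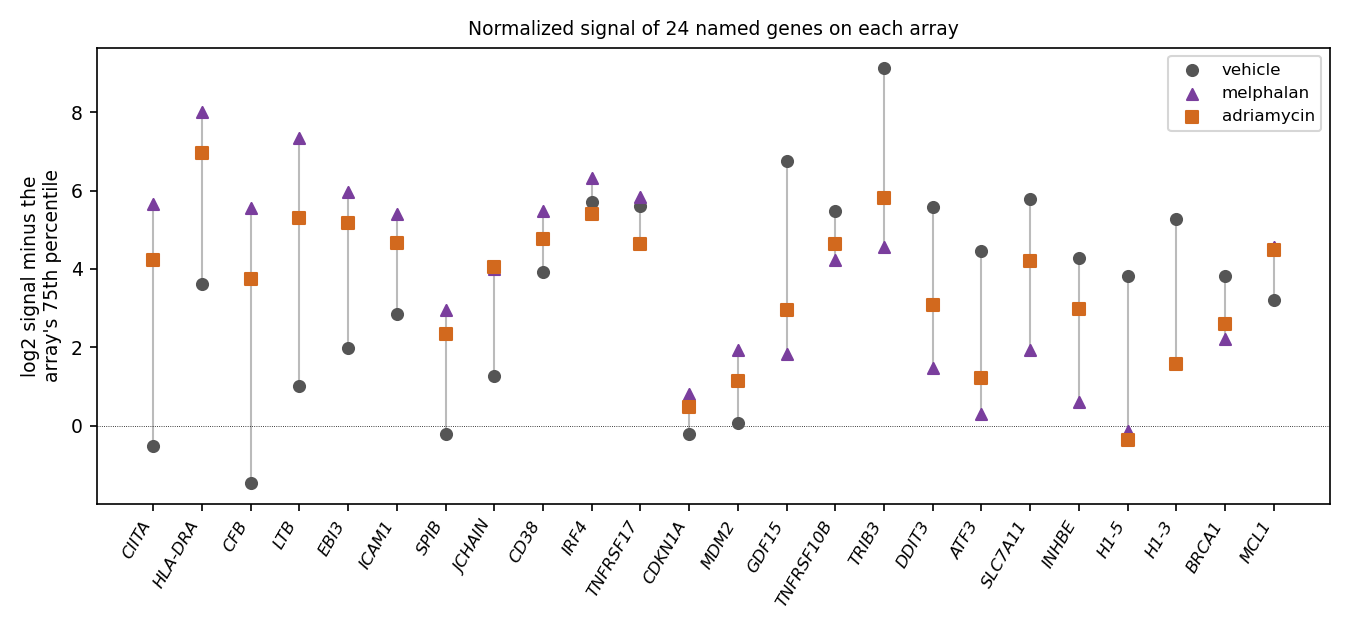
Normalized signal (log2 minus the array's 75th percentile, vertical axis) of 24 named genes on the vehicle, melphalan and adriamycin arrays, 1 point per array with no error bars, and the H1-3 melphalan point lies under the adriamycin point. CIITA and HLA-DRA are highest with melphalan and lowest with vehicle, and TRIB3, DDIT3 and INHBE are highest with vehicle and lowest with melphalan.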

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

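All of the tests used in weighing the patterns below were chosen after the results were seen. Values with opposite signs under the drugs drew attention, and none of these differences was tested. Mitosis genes had a median of -0.22 with melphalan and 0.21 with adriamycin (-0.69 and 0.00963 under spiked-in scaling). IRF4 stood at 0.62 and -0.31, TNFRSF17 at 0.24 and -0.96, MYC at -0.0723 and 0.30, and TLR1 at -1.03 and 1.02 (spot errors 0.38 and 0.15). The spiked-in control probes were not among the genes compared. The 7 of them well above background were on average 0.47 (SD over probes 0.03) higher after normalization with melphalan and 0.20 (SD over probes 0.04) higher with adriamycin, each in 7 of 7 probes.

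Antigen presentation genes were higher with both drugs (medians 1.29 and 1.13). B cells or monocytes mixed into the treated cultures could bring such transcripts: the first test, the median of 10 B cell identity genes, gave 0.97 with melphalan (0.47 with bounds) and left this open. A count added after that median was seen does not settle it either: of 31 B cell and monocyte markers on the array 7 were at least 2-fold higher with melphalan and 5 with adriamycin, but 16 were dim on all 3 arrays and no table says how many such cells would raise. RNA of another line as the main content of the drug arrays is argued against by the cancer testis antigen genes, if these differ widely between lines, which was assumed. Within 2-fold of vehicle were 11 of 13 with melphalan and 12 with adriamycin. The exceptions were DAZL, 6.41 and 5.22 higher, and SSX1, at -1.08 with melphalan. Of all genes, 19.4% were called with melphalan and 15.0% with adriamycin, so these genes did not stand out as stable. The median between the drug arrays was -0.50 (SD of matched lists 0.06, -0.22 under spiked-in scaling), so those arrays differed from each other too. That comparison does not use the vehicle array, so it cannot say whether an unusual vehicle array gave the rise shared by both drugs. A response of these genes to the drugs, an admixture of cells, an unusual vehicle array, and differences between single cultures all stay open.

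Unfolded protein response genes were lower with both drugs (medians -0.98 and -1.04). Amino acid shortage in the vehicle culture, left for 5 days without drug, may have raised part of them there: the amino acid response genes outside the list, some of which had been seen to be lower before that list was written, had a median of -2.12 with melphalan and -1.07 with adriamycin, 20 of 23 being at least 2-fold lower with melphalan. Their values cannot tell amino acid shortage from another stress that raises the same genes. The vehicle culture alone does not account for the difference between the drug arrays, where 26 of 27 amino acid response genes were higher with adriamycin (median 2.14-fold). Endoplasmic reticulum chaperone genes, taken as genes that amino acid shortage does not raise, stood at -0.69 with melphalan and -0.74 with adriamycin. The SD of matched lists was 0.15 and 0.13, and 19 of 20 lay below 0 with each drug. They argue against amino acid shortage as the cause for these genes. Of the 20, 16 belong to the unfolded protein response list and so are no separate pattern. Hypoxia genes, at 0.0806 with 3 higher and 3 lower, do not settle oxygen shortage, since spiked-in scaling moves all medians by -0.47. An effect of the drugs stays open for both parts, and so does a stress other than amino acid shortage in the vehicle culture, which was not tested. Amino acid shortage in the vehicle culture stays open for the amino acid response part. That culture was measured once.

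Replication-dependent histone genes were lower with both drugs (medians -1.76 and -1.98). Scaling is argued against, since over both drugs and all scalings and normalizations the median was at most -1.64, and averaging a gene's probes, which is not a scaling, gave -1.45 with melphalan and -1.53 with adriamycin. A smaller share of cells in S phase could lower them. DNA replication and S phase genes were lower with adriamycin too, at -0.35 (SD of matched lists 0.11), but by less, and no table says by how much these lists should differ, so it cannot be told apart from a drug effect on histone transcripts themselves. How well the cRNA labelling captured histone transcripts on each array was not examined, and other explanations were not tested.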

How the results depend on the processing

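No paired analysis was possible because each group has 1 array and no result comes from a test, and no replicate could be left out. Quantile normalization, the deposited value table, the mean of a gene's probes and the percentile over detected probes (this last chosen after seeing the data) left every count within 1.5 times its value and r within 0.05. So did scaling on the median. No called named gene took the other sign under any alternative. Only normexp, quantile normalization and the mean of a gene's probes could have changed such a sign. The other scalings moved all genes together, by -0.47 at the most, and a call needs a size of at least 1. The filters and the threshold leave gene values as they are. Counts moved with the treatment of dim probes, with the threshold and with spiked-in scaling. The cause of each shift below was not tested, except where fewer or more genes entered or the threshold was raised.

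With normexp and quantile normalization, whose offset shrinks differences of dim probes by construction, 980 genes were higher and 701 lower with melphalan, 612 and 464 with adriamycin, 35 and 182 with adriamycin over melphalan, and 526 and 388 with both drugs, with r = 0.90. Restricting to genes well above background on all 3 arrays gave 161 higher and 364 lower with adriamycin over melphalan, r = 0.89 and a median of -0.0104 for immediate early genes with melphalan. Without a filter, 4601 were higher and 3326 lower with melphalan, 3968 and 3107 with adriamycin, 1504 and 2431 with adriamycin over melphalan, and 2443 and 2007 with both, with r = 0.77. At a threshold of 1.5 the counts were 1343 and 714, 891 and 507, 67 and 227, and 720 and 358 in the same order.

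Scaling on spiked-in controls, chosen after seeing the data, gave 1385 higher and 4844 lower with melphalan, 2298 lower with adriamycin, 853 higher and 392 lower with adriamycin over melphalan, and 944 higher and 2098 lower with both. This scaling moved every list median by -0.47 with melphalan, -0.20 with adriamycin and 0.28 with adriamycin over melphalan. The medians that took the other sign from outside the central 95% of random lists were, with melphalan, p53 targets (-0.20), NK and T cell ligands (-0.12), BCL2 family (-0.0476), glycolysis (-0.11) and lysosome genes (-0.0944). With adriamycin over melphalan they were p53 targets (0.0948), histones (0.20), oxidative phosphorylation (0.18), lysosome (0.13) and adhesion genes (0.0726). Across the 9 alternatives other than the threshold, antigen presentation genes ranged from 0.82 to 1.47 with melphalan and 0.94 to 1.22 with adriamycin, unfolded protein response genes from -1.45 to -0.85 and -1.23 to -0.90, and histones from -2.23 to -1.45 and -2.18 to -1.53. NF-kB target genes ranged from 1.03 to 1.93 and 0.48 to 0.91, and adhesion genes from 0.52 to 1.72 and 0.34 to 1.28. All 90 list medians stayed about the same with the deposited value table, which repeats the main scaling, and with no filter. Neither is a separate check of these ranges.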

Other observations

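Genes of the amino acid response, a list of 30 written after the fixed lists had been seen, were mostly lower with both drugs. Of 27 measured members 24 were at least 2-fold lower with melphalan and 2 higher (median -2.20), and 18 were lower with adriamycin and 2 higher (median -1.12). With adriamycin over melphalan, which does not use the vehicle array, 26 of 27 lay above 0 and 14 were at least 2-fold higher (median 2.14-fold). Some members had been seen to be lower with the drugs before the list was written, so these values only describe the chosen genes. The asparagine synthetase gene ASNS stood at -3.03 and -1.23, the transcription factor gene CEBPB at -3.25 and -2.08, and the alanyl-tRNA synthetase gene AARS1 at -2.12 and -1.02. The members higher with both drugs were ATF5 (2.64 and 2.35) and NUPR1 (2.15 and 2.76). The list shares 4 genes with the unfolded protein response list, 2 with the drug transporter list and 1 each with the p53 target and oxidative stress lists.

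Endoplasmic reticulum chaperone genes, 16 of 20 of them also in the unfolded protein response list, had medians of -0.69 and -0.74 and differed little between the drugs (-0.09). Hypoxia genes had medians of 0.08 and 0.03, or 0.01 and 0.02 with bounds, with 3 higher and 3 lower of 21 with melphalan. Among them ANKRD37 was 2.61 higher with melphalan and VEGFA stood at -1.27. B cell identity genes had medians of 0.97 and 0.81, or 0.47 and 0.80 with bounds, with BLK at 2.69 and 1.90.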
